A study of Mus musculus with 4 samples.

How the data were processed

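Dendritic cells were grown from C57Bl/6 mouse bone marrow with GM-CSF and stimulated for 16 h with media or poly I:C (10 µg/ml) under normoxia or hypoxia (0.5% per the labels, which do not name the gas). Total RNA (200 ng) was amplified by random priming, labelled with biotin and read on Affymetrix Mouse Gene ST 1.0 arrays, per the labels' protocols. That protocol text also mentions nascent RNA, whereas all 4 samples are labelled total RNA, and they were treated as total RNA here. Each condition has 1 array. Per the series' design text and the submitters' processing notes, the array files were normalized by RMA (robust multi-array averaging) with Affymetrix Expression Console. RMA corrects background, makes the intensity distributions of the arrays alike and summarises the probes of a probe set. Versions of these tools and the genome build of the annotation are not given in the sources used here, so no coordinates are printed.

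The deposited values are RMA intensities on a linear scale, 28998 probe sets by 4 arrays, with medians of 3.90 to 4.09 and maxima of 7225 to 8810. The same intensities were deposited in 2 tables, a text table and a series matrix, and 0 values differed between them. The text table also holds, per the file headers, a rank order that the authors gave to 548 probe sets, which was used here as a deposited score. All 548 have a highest minus lowest intensity of at least 80 and a highest over lowest ratio of at least 3, and no other probe set meets both, which was tested on the table. It further holds 4 columns of per-sample Z-scores, which were not used.

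The comparisons had been planned for log2 values. Because the values turned out to be linear, log2 was taken first and the planned floor of 6 on the log2 scale was kept, which is an intensity of 64. A gene entered when its highest value over the 4 arrays reached the floor, a rule that does not look at which array is high. It can still admit a gene because that gene is high in 1 condition, which favours a difference in that direction. Probe sets were named through their RefSeq accessions with a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the 28998 probe sets 18694 matched by accession, 2210 through a current symbol and 1750 through a synonym, and 2270 kept the symbol in the file. A further 163 had several genes and 3911 had none, and these were left out. The 24924 named probe sets gave 22221 genes, of which 2714 passed the floor. Of those, 392 had more than 1 probe set, and the brightest was used. Among leading genes with several probe sets above the floor, which are H3c13, Kpna2, Stmn1 and Tgtp1, the probe sets gave the same direction wherever any of them reached 2-fold. Averaging probe sets moved 30 of the values of list members and leading genes by 0.32 or more, those of Cflar, Cycs, Dnaja1, Ear1, H2-Q8, Hspa8, Nlrc5, Pclaf, Psme2, Rpl23 and Rps15. The ND3 probe sets differ and are given with that gene. Ak3l1 is printed as the file names it.

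For each pair of conditions the log2 difference was computed per gene and counted as a call at 2-fold or more. With 1 array per condition no difference between 2 arrays has a replicate error, no pairing exists, and the number of arrays limits the precision. An additive fit of both factors, whose residual would be the difference of differences, was not run, because that residual contains any response to the combination, and no p-value is given. Where comparisons share no array, the overlap of calls was set beside the overlap of independent lists of those sizes, and the correlation and slope were taken across genes. The difference of differences is hypoxia minus normoxia with poly I:C, minus the same in media. Its robust SD over genes, 0.45, was taken as a measure of the noise of 4 arrays together, and it contains any real response to the combination.

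Before the data were examined, 22 pathway lists and 12 lists of cell type markers were fixed, with the floor, the threshold, the alternatives and the rule for named genes. That rule takes the 10 genes with the largest increase and the 10 with the largest decrease in each comparison, among genes above the floor with a named symbol, plus list members, starting with up to 4 of largest absolute difference. A few genes that the rule takes are not reported here, so runs of named genes can skip some. Genes named outside it are said to be so chosen. For each list with at least 5 genes above the floor the median was placed among 10000 random lists of the same size, matched in 10 strata of mean expression. Lists can share genes, for example Irf7, Ifih1, Ddx58, Zbp1 and Eif2ak2 in the sensor and interferon-stimulated lists. Cxcl9 and Cxcl10 are both interferon-stimulated and chemokine list members. Il15 and Ccl22 stand in the cytokine and maturation lists, and Slc2a1 in the HIF and glycolysis lists. Results of such lists are not independent of each other.

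The steps were tested on simulated data. Differences with a spread of 0.32 were drawn for the 2714 genes, 50 of them altered at each fold. For hypoxia in media 52% of genes simulated at 2-fold, 96% at 3-fold and 100% at 4-fold were called, with 3 false calls among 2514 unaltered genes. For hypoxia with poly I:C the shares were 42%, 92% and 100%, with 4 false calls. Of 100 simulated lists of 20 unaltered genes 7 lay outside the middle 95% of random lists. The simulated noise was independent between genes, with the same spread for every gene, taken from these arrays. The simulation therefore checks the steps under such noise only. It gives no error rate for real lists, whose genes can move together within a culture.

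The alternatives were no floor, a floor of 7, thresholds of 1.5-fold and 3-fold, the mean of all probe sets, genes with a single probe set, the series matrix, cyclic loess between arrays (limma 3.58.1 in R 4.3.3), centring on the median of expressed genes or on the reference genes, list means, and random lists without matching. A floor of 4, an intensity of 16, was added after the values were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.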

Results

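Bone marrow cells of C57Bl/6 mice were grown into dendritic cells with GM-CSF and then held for 16 h in 1 of 4 conditions, which crossed oxygen level with stimulation. The conditions were normoxia in media, normoxia with poly I:C at 10 µg/ml, hypoxia in media, and hypoxia with poly I:C. Poly I:C is a synthetic double-stranded RNA that cells sense much as they sense viral RNA. The labels give the hypoxia as 0.5% without naming the gas. Total RNA of each condition was read on 1 Affymetrix Mouse Gene ST 1.0 array, a whole-transcript array. With 1 array per condition there were no replicates, so no difference given here has a replicate error, a p-value or a replicate check, and the number of arrays limits the precision of every value. Median intensities of the 4 arrays lay between 3.90 and 4.09, and the highest intensities between 7225 and 8810. Of 22221 genes with a symbol, 2714 reached an intensity of 64 on at least 1 array, and the comparisons cover these genes unless stated otherwise. "Higher" and "lower" as counts mean a difference of at least 2-fold, and values are log2 differences between 2 arrays. A list's percentile places its median among 10000 random lists matched on expression and describes these arrays only.

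Across the 2714 genes, the arrays with poly I:C were closest to each other (r = 0.905), followed by the arrays in media (r = 0.873). Correlations between an array in media and an array with poly I:C lay between 0.521 and 0.659. These correlations are across genes, which are not independent replicates. The difference of differences, formed from all 4 arrays, had a robust SD of 0.45 over genes, which corresponds to 0.32 for a single difference between 2 arrays if no gene responded to the combination. The 2-fold threshold is 3.15 times that value for a single difference, and a smaller multiple of the 0.45 for the difference of differences.

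Transcripts of the myeloid lineage were abundant on all 4 arrays. Of 12 dendritic cell markers 5 were above the floor, among them Itgax, which encodes CD11c, at intensities of 268.1 to 615 and Cd74, the invariant chain of MHC class II, at 772 to 1128. Of 17 macrophage markers 15 were above the floor, including Lyz2 at 2856 to 3543 and Csf1r, the receptor for macrophage colony-stimulating factor, at 448 to 948. Of 20 markers of neutrophils and their precursors 2 passed, Mmp8 (95.3 to 580.1) and Chil3 (349 to 484). The eosinophil list gave Ear1 and Ear2 at up to 179 and 275, the erythroid list gave Car2 at up to 167, and the megakaryocyte and platelet list gave Ppbp at up to 110.4 and Vwf at up to 68.1. No marker of plasmacytoid dendritic cells, mast cells and basophils, B cells, T cells, natural killer cells or stromal cells reached the floor. Some of these markers differed between conditions, and the values of macrophage markers, Mmp8 and Ppbp stand with the comparisons. Car2 was higher with poly I:C in normoxia (2.28) and in hypoxia (1.03) and lower for hypoxia with poly I:C (-1.12). Ear1 and Ear2 were both 2-fold higher with poly I:C in hypoxia and with both treatments together. Vwf was higher in hypoxia in media (1.06) and lower with poly I:C in hypoxia (-1.18), and the dendritic cell marker Fgl2 was at 3.14 with poly I:C in normoxia, 4.50 with it in hypoxia and -1.72 in hypoxia in media.

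The comparison of poly I:C with media in normoxia asked how dendritic cells respond to double-stranded RNA at ambient oxygen. With poly I:C, 402 of the 2714 genes were higher and 194 were lower. The balance followed the processing, with 483 and 124 after centring on the reference genes and 642 and 636 without a floor. The genes furthest above the media array were mostly interferon-induced. Slfn4, a Schlafen family gene (probe set 10379636), read 1307 against 7.62, a log2 difference of 7.42. Rsad2, which encodes the antiviral protein viperin, read 1403 against 14.7 (6.57), and the chemokine gene Cxcl10 read 1218 against 15.7 (6.28). Ms4a4c (6.71), Ch25h (6.45), Ifi205, Cmpk2 (6.12), Ifit3 (6.02), Isg20 (5.94) and Ifit3b made up the remaining leading genes. The media readings of these 10 genes were low, so their folds rest on a dim denominator, and the near-identical Ifit3 and Ifit3b cannot be assumed to be read separately. At the other end, Ppbp, a platelet chemokine gene, read 3.12 against 110.4 (-5.14), and Fn1, which encodes fibronectin, read 60.8 against 1331 (-4.45). Plxdc2 (-3.52), the mannose receptor gene Mrc1 (-3.51), the linker histone gene H1f5 (-3.40), Mamdc2 (-3.38), Hmgcs1 (-3.00), Sort1 (-2.93) and Pclaf (-2.92) were also far lower.

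By list, 53 of 54 interferon-stimulated genes were higher with poly I:C in normoxia, none was lower, and the median was 3.12 (percentile 100). The gene short of 2-fold was Irf9 at 0.84. Of 22 genes of MHC class I and its loading machinery 17 were higher (median 1.89, percentile 100), led by H2-Q6 (4.10), H2-T22 (3.46), the peptide transporter gene Tap1 (2.57) and the immunoproteasome gene Psmb9 (2.44). The MHC class II list did not follow: its 10 genes had a median of 0.08 and none was 2-fold apart. Of 19 inflammatory cytokine and chemokine genes 13 were higher (median 1.85, percentile 100), with Cxcl10, Cxcl9 (5.02), Ccl5 (4.54) and Tnfsf10 (3.95) furthest apart and Tnf at 1.85. None of the 11 type I interferon genes on the array reached the floor in any condition, so the interferon transcripts themselves were not measurable at this signal. Of 11 genes of dendritic cell maturation and co-stimulation 9 were higher (median 1.66, percentile 100), including the co-stimulatory ligand gene Cd86 (3.30), Il15ra (2.77), Il15 (2.02) and Fscn1 (1.94). The array held 28 listed maturation genes and 39 listed cytokine and chemokine genes, of which these 11 and 19 passed the floor. Fscn1 and the cytokine list's Edn1 did so with poly I:C in normoxia only, and such admission favours higher values there. Of 18 genes for nucleic acid sensors and their adaptors 10 were higher (median 1.04), among them Irf7 (5.14), Zbp1 (3.18) and Ifih1 (2.55). The NF-kB feedback list had 6 of 16 genes higher (median 0.69), led by Ptgs2, the inducible cyclooxygenase gene (4.18). The apoptosis list had 7 of 12 higher (median 1.07), led by Casp4 (2.28).

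Metabolic lists also differed with poly I:C in normoxia. Of 10 genes of cholesterol synthesis and uptake 9 were lower, with a median of -1.74 (percentile 0). Examples were Hmgcs1, Idi1 (-2.43) and Sqle (-2.15). Of 32 HIF target genes, which respond to hypoxia-inducible factors, 14 were higher with poly I:C at normoxia (median 0.90, percentile 99.99). Nos2, the inducible nitric oxide synthase gene, was at 4.35, Arg1, which encodes arginase, at 2.66, Egln3, a prolyl hydroxylase gene of the HIF pathway, at 2.10 and Ankrd37 at 1.84. Without a level floor the HIF list's median was 0.23. Of 18 glycolysis genes 6 were higher and 1, Aldoc (-2.15), was lower (median 0.80). Of 46 cytosolic ribosomal protein genes 4 were lower, Rpl3 (-1.40), Rpl10a (-1.23), Rpl5 (-1.16) and Rpsa (-1.06), and the median was -0.49 (percentile 0), or -0.25 with cyclic loess scaling, which moved the median of all genes from -0.03 to 0.16. Of 7 amino acid response genes 4 were higher, led by Asns (2.10), but the median of 1.01 lay inside the middle 95% of random lists (percentile 94.02), and at 98.84 among random lists not matched on expression. Of 14 endoplasmic reticulum chaperone genes 2 were lower, Herpud1 (-1.15) and Hsp90b1 (-1.02), with a median of -0.67, or -0.40 with cyclic loess. The 13 other Toll-like and C-type lectin receptor genes went both ways, with 3 higher, led by Clec4e (1.98), and 4 lower, among them Mrc1, the scavenger receptor gene Marco (-1.75) and Cd36 (-1.30). Among cell type markers, the macrophage list's median was -0.26, and it turned to 0.02 with cyclic loess scaling. Its members ranged from the Fc receptor gene Fcgr1 at 3.90 to Mrc1 at -3.51, and the neutrophil marker Mmp8 was at -2.03.

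The comparison of hypoxia with normoxia in media asked what low oxygen does without stimulation. In hypoxia 145 genes were higher and 184 lower, and at a 3-fold threshold 67 and 58. Arg1 (probe set 10368343) read 796 against 5.76, a log2 difference of 7.11, and Egln3 (probe set 10400304) read 506 against 3.81 (7.05). They were followed by Ndrg1 (5.04), Selenbp1 (4.59), the co-stimulatory receptor gene Tnfrsf9 (4.53), F13a1, which encodes a coagulation factor subunit (4.24), Ankrd37 (4.19), the endoplasmic reticulum oxidase gene Ero1a (4.18), Ak3l1 (4.01) and the glycogen synthase gene Gys1 (3.83). At the other end, Ccl2, a chemokine gene that draws monocytes, read 3.50 against 74.5 (-4.41). Pclaf, a gene of dividing cells, was at -3.41, Apol7c at -3.30 and H1f5 at -3.07. The interferon-induced Rtp4 (-2.62), Ppbp (-2.58), Ly6i (-2.46), the nuclear import gene Kpna2 (-2.39), Adgre4 (-2.39) and the lectin receptor gene Clec5a (-2.37) followed.

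Of the 32 HIF target genes 30 were higher in hypoxia in media and none was lower, with a median of 2.54 (percentile 100). The remaining genes were Cited2 (0.98) and Plin2 (0.85). Of 53 listed HIF target genes on the array 32 passed the floor, and members such as Egln3, Selenbp1 and Ndrg1 did so in hypoxia only. Admission by being high in hypoxia favours higher values there. Vegfa, the angiogenic growth factor gene, was at 2.97, and the glucose transporter gene Slc2a1 at 2.54. Of the 18 glycolysis genes 15 were higher (median 1.68, percentile 100), among them Hk2 (2.53), Tpi1 (2.36), Pfkl (2.29) and the lactate exporter gene Slc16a3 (2.41). The 24 nuclear-encoded genes of oxidative phosphorylation had a median of -0.18, and 2 were lower, Cycs, which encodes cytochrome c (-1.95), and Cox5a (-1.17). Of the reference genes Pgk1 (1.71) was higher, Gapdh was at 0.93 and Actb at -0.06, and the first 2 belong to glycolysis.

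Interferon-stimulated genes lay below the normoxic array: 21 of 54 were lower in hypoxia in media, none was higher, and the median was -0.86 (percentile 0). Rtp4, Ly6a (-2.20), Cxcl10 (-1.94) and Oasl2 (-1.83) were furthest down. Some members were dim on both media arrays, normoxia and hypoxia, such as Cxcl10 (15.7 and 4.09), Ifit1 (16.1 and 5.22) and Ifit3 (9.02 and 3.10). Their folds rest on signal near background. The random lists were matched on the mean over the 4 arrays, not on the level in media. Of the 19 inflammatory cytokine and chemokine genes 7 were lower (median -0.69, percentile 0.09), led by Ccl2, with Edn1 (-1.55), Ccl3 (-1.40) and Ccl5 (-1.27) next apart from Cxcl10. Of the 18 nucleic acid sensor genes 3 were lower, Ikbke (-1.64), Ddx58 (-1.56) and Tlr7 (-1.13), and the median was -0.56 (percentile 0.13). The NF-kB list was mixed (median -0.24), with Ier3 at 2.70 and Marcksl1 (-1.96) and Sod2 (-1.68) lower. Among maturation genes 3 of 11 were lower, Marcksl1, Marcks (-1.48) and Fscn1 (-1.23). Of the other Toll-like and C-type lectin receptors 3 were lower, Clec5a, Marco (-2.09) and Mrc1 (-1.39), and Mgl2 was higher (1.32), with a median of -0.56 (percentile 0.76). MHC class I genes had a median of 0.00 (-0.07 to 0.07 by scaling), with 3 lower, Erap1 (-1.49), Psme2 (-1.07) and Nlrc5 (-1.03), and MHC class II genes a median of 0.38 (percentile 98.96) with none at 2-fold. Of the 14 endoplasmic reticulum chaperone genes 4 were lower (median -0.73, percentile 0.03), Hyou1 (-1.39), Pdia6 (-1.32), Hspa5 (-1.26) and Sdf2l1 (-1.22). Of the 10 cholesterol genes 4 were lower (median -0.73, percentile 3.52), with Hmgcs1 at -1.84 and Idi1 at -1.78. The heat shock list had 1 of 6 genes lower, Hspd1 (-1.19), with a median of -0.66 (percentile 0.55). The oxidative stress list went both ways: Mt2 (2.16), Hmox1 (1.20) and Mt1 (1.02) were higher and Sod2, Gclm (-1.36), Txnrd1 (-1.17) and G6pdx (-1.17) were lower. Apoptosis genes (median -0.34), amino acid response genes (-0.46), ribosomal protein genes (0.12, percentile 99.49) and lysosomal genes (0.10) gave at most 1 call in each direction. The macrophage markers had a median of -0.09, with Apoe at 1.27, Mrc1 at -1.39 and Fcgr1 at -1.08.

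The comparison of hypoxia with normoxia in the presence of poly I:C asked how low oxygen bears on stimulated cells. Here 108 genes were higher and 100 lower, against 96 and 123 after centring on the reference genes, so neither direction prevailed under all settings. Selenbp1 (4.91), Egln3 (3.92), the collagen hydroxylase gene P4ha2 (3.72), the lipid droplet gene Hilpda (3.26), Ndrg1 (3.06), Gys1 (2.86), the metallothionein gene Mt2 (2.80), Impa2 (2.66) and Ero1a (2.62) were among the genes furthest above the normoxic array. Apol7c was furthest below at -3.89. Fscn1, which encodes the actin-bundling protein fascin of mature dendritic cells, read 18.8 against 121.5 (-2.70), followed by Cacnb3 (-2.41), the endothelin gene Edn1 (-2.39), Cd300ld (-2.04), Prkcb (-1.96), Spint1 (-1.91), the mitochondrially encoded CYTB (-1.84), Plxnc1 (-1.81) and Kcnk6 (-1.80). Fscn1, Cacnb3 and Edn1 reached the floor with poly I:C in normoxia only. Such admission favours lower values in this comparison, also where Fscn1 and Edn1 count in a list below.

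Of the 32 HIF target genes 25 were higher with poly I:C and none was lower (median 1.49, percentile 100), and of the 18 glycolysis genes 8 were higher (median 0.98, percentile 100). HIF members such as Selenbp1, P4ha2 and Hilpda passed the floor in hypoxia only, which favours higher values there. Arg1 was at 2.36, Vegfa at 1.44, Nos2 at 1.92 and Slc2a1 at 0.97. No interferon-stimulated gene was 2-fold apart, and the list's median was 0.11 (percentile 97.6), or 0.04 to 0.14 by scaling. MHC class I genes had a median of 0.32 (percentile 99.89) and MHC class II genes a median of 0.33 (percentile 99.47), again with no call. Of the 11 maturation genes 4 were lower, Fscn1, Marcks (-1.75), the chemokine receptor gene Ccr7 (-1.26) and Ccl22 (-1.07), and Il15 was higher (1.02). Of the 19 cytokine and chemokine genes 3 were lower, Edn1, Ccl2 (-1.41) and Ccl22 (median -0.47, percentile 0.13), and Tnf was at -0.92. Of the 13 other Toll-like and C-type lectin receptors 5 were lower (median -0.49, percentile 0.15), Clec5a (-1.41), Mrc1 (-1.26), Clec7a (-1.25), Clec4a2 (-1.22) and Cd36 (-1.10). In the oxidative stress list Mt2, Mt1 (1.57) and Hmox1 (1.10) were higher and Gclm (-1.50) and Slc7a11 (-1.02) lower, with a median of -0.38 (percentile 0.12). The sensor (-0.03), NF-kB (0.19), chaperone (-0.10), heat shock (-0.22), apoptosis (0.11), oxidative phosphorylation (-0.14), ribosomal (0.03), cholesterol (0.04) and reference gene (0.06) lists had the medians in brackets and at most 1 call each. Of these, the sensor, ribosomal, cholesterol and reference gene medians changed sign under other scalings. Among macrophage markers Mertk (-1.18) and Mrc1 were lower.

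**Figure D1:**
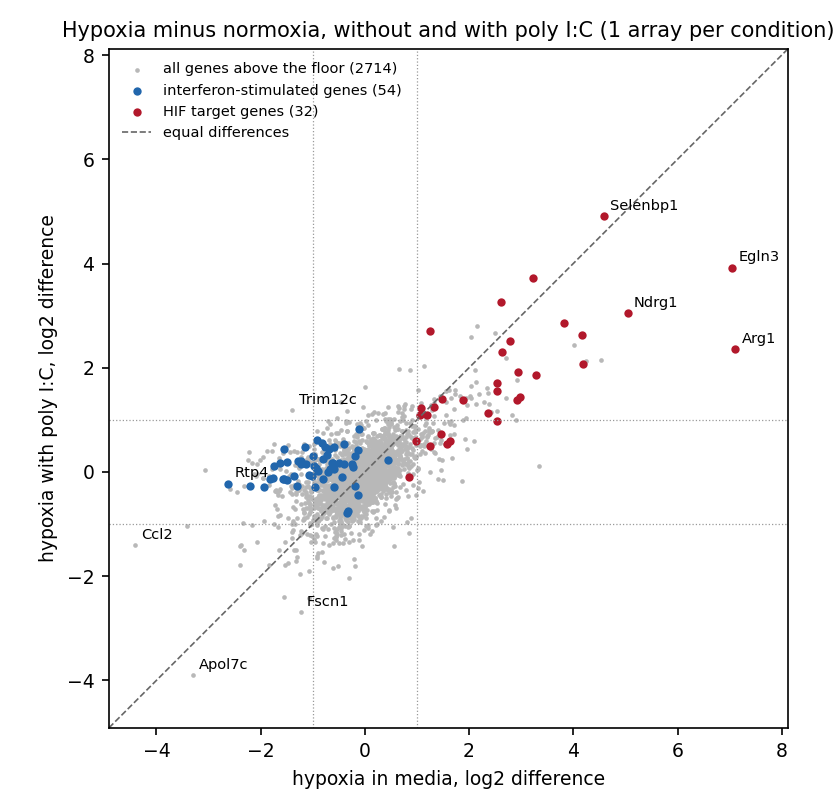
Each point is 1 of the 2714 genes above the floor, placed by its log2 difference between hypoxia and normoxia in media (horizontal) and with poly I:C (vertical). Dotted lines mark 2-fold and the dashed line equal differences. HIF target genes (red) lie to the right in media with a median of 2.54 and at a median of 1.49 with poly I:C, and interferon-stimulated genes (blue) spread to the left of 0 in media and around 0 with poly I:C.

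The hypoxia differences in media and with poly I:C share no array. They had 76 higher genes in common where 5.77 would be shared by independent lists of those sizes, and 37 lower genes where 6.78 would. Across the 2714 genes r was 0.63 and Spearman's rho 0.52, and the slope of the difference with poly I:C on that in media was 0.49. Only Trim12c was 2-fold lower in media (-1.39) and 2-fold higher with poly I:C (1.19). Genes are not independent replicates, and no p-value is given for either measure.

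The comparison of poly I:C with media in hypoxia asked for the response to double-stranded RNA at low oxygen. With poly I:C 447 genes were higher and 261 lower. The lower count was 171 after centring on the reference genes, 172 with cyclic loess and 358 with median centring. Ms4a4c read 1065 against 3.90 (8.10), Ifit3 796 against 3.10 (8.01) and Cxcl10 1002 against 4.09 (7.94). Ifi205 (7.74), Ifit2 (7.44), Cmpk2 (7.40), Tgtp1 (7.12), Slfn4 (7.10), Ifit1 (7.09) and Ifi206 (6.88) followed. Mamdc2 read 6.54 against 226 (-5.11), and F13a1 was at -4.24, Fn1 at -4.18, Mrc1 at -3.38, Sort1 at -3.25, Plxdc2 at -3.21, the isocitrate dehydrogenase gene Idh1 at -3.04, Mmp19 and Itga1 at -2.99 and Ppbp at -2.90. All 54 interferon-stimulated genes were higher (median 4.2, percentile 100). So were 18 of 22 MHC class I genes (median 2.35), 13 of 19 cytokine and chemokine genes (1.76), 7 of 11 maturation genes (1.58), 11 of 18 sensor genes (1.30), 9 of 16 NF-kB genes (1.09) and 8 of 12 apoptosis genes (1.46). Examples were Ccl5 (5.89), Ptgs2 (4.97), Cd86 (3.72) and Casp4 (3.59). The amino acid response list had 3 of 7 higher, led by Nupr1 (3.24), and its median of 0.77 lay inside the middle 95% of random lists (percentile 88.2).

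HIF target genes had no shared direction with poly I:C in hypoxia: 3 were higher, among them Nos2 (3.33) and P4ha2 (1.21), and 2 lower, Arg1 (-2.09) and Egln3 (-1.03), with a median of -0.02. Glycolysis genes had a median of 0.05, with Hk3 at 1.43 and Aldoc at -1.60, and the signs of both medians depended on the scaling. Of the 10 cholesterol genes 4 were lower (median -0.86), among them Hmgcs1 (-1.41) and Sqle (-1.18). Of the 46 ribosomal protein genes 5 were lower and 1 was higher (median -0.54, percentile 0). With cyclic loess scaling that median was -0.35. The MHC class II median was 0.02, and Lgmn, a lysosomal protease gene, was at -1.69. The chaperone list had a median of 0.06 with Dnajb11 (1.18) and Hspa5 (1.15) higher and Herpud1 (-1.23) lower, and the oxidative phosphorylation list a median of -0.19 (-0.02 with cyclic loess) with Cycs at 2.75. Under other scalings the MHC class II and chaperone medians changed sign, as did those of lysosome (-0.18), oxidative stress (-0.15) and heat shock (-0.03) genes. The other lectin receptors had 3 higher, led by Clec4e (3.13), and 3 lower, led by Mrc1. The macrophage markers had a median of -0.65 (percentile 0.32), or -0.43 with cyclic loess, with Fcgr1 at 4.94, and Mmp8 was at -2.61.

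**Figure D2:**
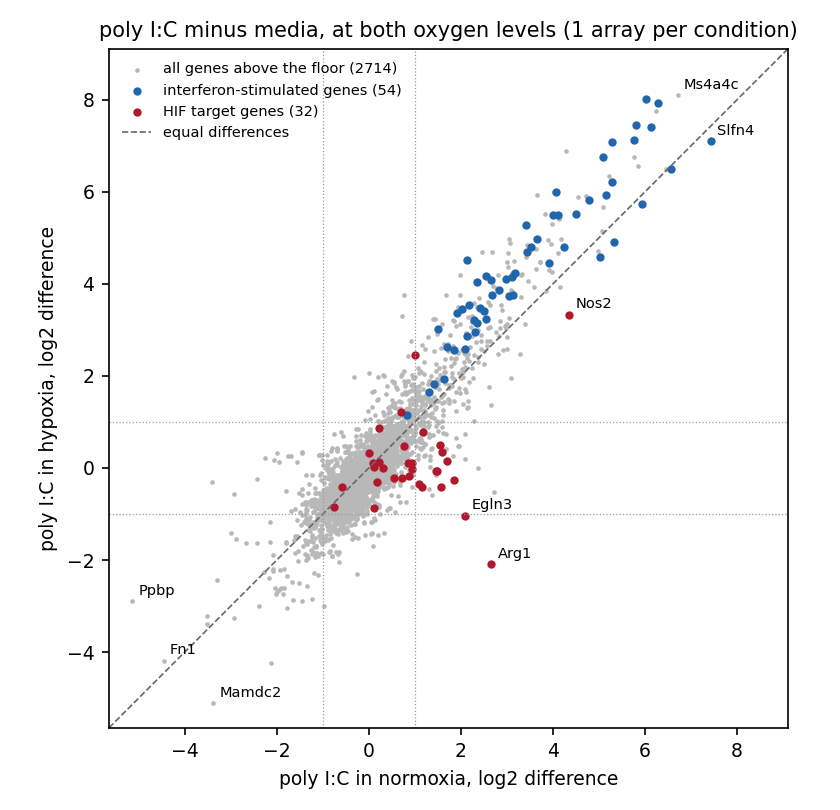
Each point is 1 of the 2714 genes above the floor, placed by its log2 difference between poly I:C and media in normoxia (horizontal) and in hypoxia (vertical). Dotted lines mark 2-fold and the dashed line equal differences. Interferon-stimulated genes (blue) lie mostly above the dashed line, with medians of 3.12 and 4.2, and HIF target genes (red) mostly below it, with Arg1 at 2.66 and -2.09.

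The poly I:C differences in normoxia and in hypoxia also share no array. They had 331 higher genes in common where 66.2 would be shared by independent lists, and 125 lower genes where 18.7 would, with r = 0.90, rho = 0.83 and a slope of 1.08 across genes. Arg1 and Egln3 were the genes called in opposite directions, each 2-fold higher with poly I:C in normoxia and 2-fold lower with it in hypoxia.

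The array with hypoxia and poly I:C together was also set against untreated cells, which gives the joint difference. In this comparison 510 genes were higher and 390 lower, but lower genes were the larger group at a floor of 4 (795 higher and 967 lower) and without a floor (941 and 1246). Slfn4 (6.97), Ifi205 (6.78), Ms4a4c (6.68), Ifit3 (6.46), Ifit3b (6.45), the guanylate-binding protein gene Gbp4 (6.31), Rsad2 (6.31), Nos2 (6.27), Isg20 (6.17) and Ch25h (6.10) were furthest above, and Ppbp (-5.48), Mrc1 (-4.77), Prkcb (-3.97), Pclaf (-3.97), the ribonucleotide reductase gene Rrm1 (-3.93), Fn1 (-3.89), Stmn1 (-3.87), Gclm (-3.59), Ptgs1 (-3.56) and Sort1 (-3.52) furthest below. Nos2 read 3.56 untreated, 72.4 with poly I:C, 27.2 in hypoxia and 274 with both. Of the 32 HIF target genes 29 were higher (median 2.68), as were 16 of 18 glycolysis genes (1.65), 53 of 54 interferon-stimulated genes (3.32), 17 of 22 MHC class I genes (2.26), 9 of 19 cytokine genes (0.93), 6 of 11 maturation genes (1.28), 9 of 18 sensor genes (1.11), 8 of 16 NF-kB genes (0.86) and 6 of 12 apoptosis genes (1.01). Of the 10 cholesterol genes 8 were lower (-1.76) and of the 14 chaperone genes 4 (-0.68). Of the 46 ribosomal protein genes 6 were lower and 1 higher (-0.41). With cyclic loess the chaperone median was -0.42, the NF-kB median 1.46 and the ribosomal median -0.18. The medians of the other lectin receptors (-0.38, percentile 15.5), oxidative stress genes (-0.45, percentile 6.19) and oxidative phosphorylation genes (-0.33, percentile 13.2) lay inside the middle 95% of random lists.

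**Figure D3:**
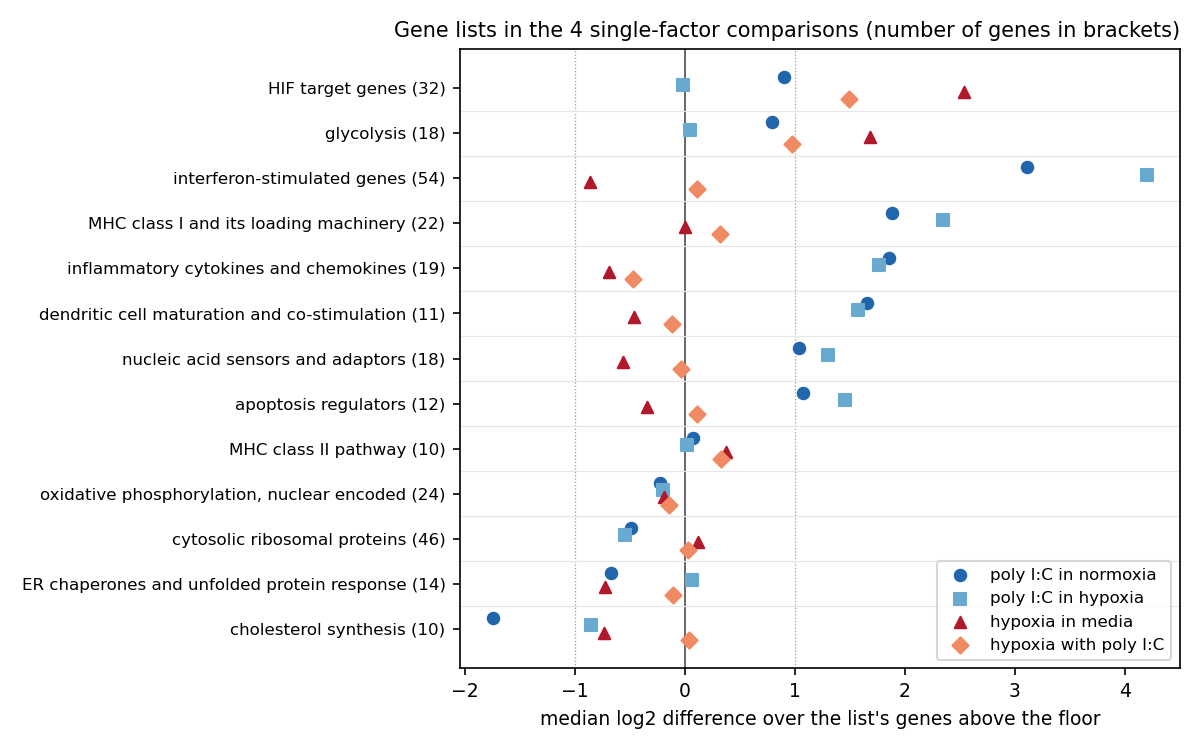
Points give the median log2 difference of 13 gene lists in the 4 single-factor comparisons, with the number of genes above the floor beside each list's name and dotted lines at 2-fold. Immune lists such as interferon-stimulated genes (3.12 and 4.2) and MHC class I (1.89 and 2.35) lie to the right with poly I:C, and HIF targets (2.54 and 1.49) and glycolysis (1.68 and 0.98) in hypoxia. Several medians close to 0 changed sign under other scalings.

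The difference of differences, hypoxia with poly I:C minus hypoxia in media, asked where the combination departs from the sum of its parts on the log2 scale. It was at least 2-fold above 0 for 160 genes and below 0 for 79. The 0.32 for a single difference was derived from its robust SD over genes of 0.45 and is smaller by construction. The 2-fold threshold is a smaller multiple of the 0.45, and the simulation did not cover this quantity. H1f5 (3.11), Ccl2 (3.0), Ifi206 (2.61), Trim12c (2.58), the histone gene H3c13 (2.49), Rtp4 (2.40), Pclaf (2.36), H3c1 (2.33), Phf11d (2.28) and Ppbp (2.25) had the largest positive values. For H1f5, Pclaf and Ppbp the sum of the parts would be an intensity of 1.18, 0.97 and 0.52, below the median of every array, so their positive values do not show a departure from it. An expected intensity below the highest array median was found for 5 of the 160 genes. For Ccl2, H3c13, Trim12c and H3c1 it was 5.96, 10.2, 11.2 and 11.2. That is above this median but under the lower floor of 16, so their values also rest on a dim expectation. Arg1 (-4.76), the cationic amino acid transporter gene Slc7a2 (-3.23), Egln3 (-3.13), Tnfrsf9 (-2.38), F13a1 (-2.12), Ankrd37 (-2.12), the phospholipid transfer protein gene Pltp (-2.04), Mmp19 (-2.02), Ndrg1 (-1.99) and Mylip (-1.97) had the most negative. Of the 54 interferon-stimulated genes 30 were above 2-fold and none below (median 1.04, percentile 100), and of the 32 HIF target genes 13 were below and 1 above (median -0.89, percentile 0). The glycolysis median was -0.74 with 2 genes below, Slc2a1 (-1.57) and Slc16a3 (-1.27). Of the 10 cholesterol genes 4 were above (median 0.91), led by Idi1 (2.19), 1 of these dim cases, and of the 14 chaperone genes 3 (0.67). MHC class I had 5 genes above (0.59), the sensors 4 (0.56), and the NF-kB list 2, Marcksl1 (1.84) and Sod2 (1.30), with a median of 0.52. Ribosomal protein genes had none (median -0.06). Eif2ak2 (1.53), Ddx58 (1.43) and Zbp1 (1.05), counted among the sensors, are also members of the interferon-stimulated list.

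The levels behind the difference of differences were as follows. Arg1 read 5.76 untreated, 36.5 with poly I:C, 796 in hypoxia and 187 with both, and Egln3 read 3.81, 16.3, 506 and 248. Cxcl10 read 15.7 untreated, 4.09 in hypoxia, 1218 with poly I:C and 1002 with both. For Rtp4 the readings in media were 63.5 in normoxia and 10.3 in hypoxia, and with poly I:C they were 276 and 236. Ccl2 read 74.5 and 3.50 in media and 127 and 47.7 with poly I:C.

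**Figure D4:**
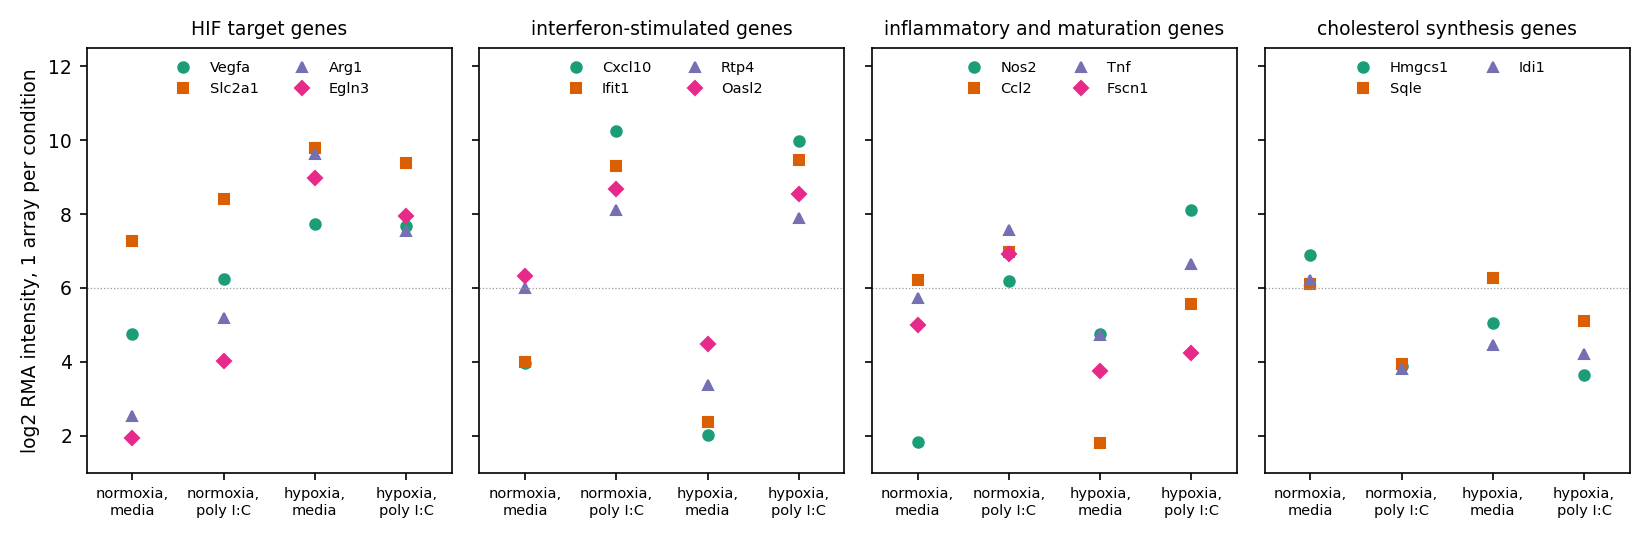
Points give the log2 RMA intensity of 15 genes on the 4 arrays, 1 array per condition, with the floor of 6 dotted. The interferon-stimulated genes Cxcl10, Ifit1, Rtp4 and Oasl2 are lower in hypoxia than in normoxia in media and nearly level at both oxygen levels with poly I:C, and Arg1 and Egln3 are highest in hypoxia in media.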

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

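In this part, the tests of the untreated culture and of a weaker hypoxic exposure were chosen only after the result was seen. None of the differences listed here was tested against replicates, since each condition has 1 array.

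Interferon-stimulated genes differed between the 2 hypoxia comparisons: their median was -0.86 in media and 0.11 with poly I:C, and the median difference of differences was 1.04, untested. A signal ceiling on the poly I:C arrays would leave the dimmer genes of the list lower in hypoxia there as well, but the 27 dimmer genes had a median of 0.18 with poly I:C (order-statistic interval 0.06 to 0.43), above the bound of -0.43. Chosen by their level on the hypoxia array instead, they had a median of 0.17. Array-wide scaling of the media arrays is also argued against, because the list's median in media stayed at -0.80 or below under all 3 other scalings. Some members, such as Cxcl10 and Ifit1, were dim on both media arrays, so their differences in media rest on signal near background. A raised interferon tone in the single untreated culture cannot be told apart from an effect of oxygen, since there is only 1 untreated array. Lower tonic interferon signalling in hypoxia without stimulation therefore stays a hypothesis, and it may equally be a property of that culture.

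HIF target genes showed a smaller hypoxia difference with poly I:C, with Arg1 and Egln3 as the extreme cases. Poly I:C went with more Arg1 in normoxia (2.66) and less in hypoxia (-2.09), a difference of differences of -4.76, and Egln3 gave 2.10 and -1.03, a difference of -3.13, both untested. A weaker hypoxic exposure of the culture with poly I:C should also lower, in hypoxia, members that poly I:C did not move in normoxia. The 8 such members had a median poly I:C difference in hypoxia of 0.0721 with an interval of -0.87 to 0.88, which leaves it open. A signal ceiling at bright probe sets is also open, since the 16 members below 8 on both hypoxia arrays had a median of -0.44 (interval -0.995 to 0.32). A candidate biological explanation is that poly I:C alone engages part of the HIF programme in normoxia, where the list's median was 0.90. Without a floor that median was 0.23, and no test here bears on this explanation. The single untreated array enters the hypoxia difference in media, the poly I:C difference in normoxia and the difference of differences. A property of that culture therefore cannot be told apart here either. The poly I:C difference in hypoxia, which does not use it, had a median of -0.02.

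Trim12c was 2-fold lower in hypoxia in media (-1.39) and 2-fold higher in hypoxia with poly I:C (1.19). The difference of differences of 2.58 was not tested. Intensities were 17.8 untreated, 6.78 in hypoxia, 29.3 with poly I:C and 66.7 with both, and only the last reached the floor. The value in media and the difference of differences rest on a dim reading in hypoxia in media.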

How the results depend on the processing

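No paired analysis was possible because each condition has 1 array. The floor of 4 was chosen after seeing the data. Counts of calls follow the floor and the threshold by construction, since these set how many genes are tested or pass. The values below are given for no floor, a floor of 7, a floor of 4, a 1.5-fold and a 3-fold threshold, in that order. Poly I:C in normoxia gave 1278, 359, 1048, 1138 and 293 calls against 596. For hypoxia in media there were 818, 195, 627, 776 and 125 against 329. For hypoxia with poly I:C there were 537, 104, 428, 618 and 51 against 208. For poly I:C in hypoxia there were 1440, 389, 1236, 1248 and 378 against 708. For hypoxia and poly I:C together there were 2187, 498, 1762, 1496 and 434 against 900. The difference of differences gave 763, 143, 475, 624 and 67 against 239. Likewise, shared calls of hypoxia in the 2 media were 221, 67, 202, 314 and 29 against 113, and shared calls of poly I:C at the 2 oxygen levels were 738, 283, 696, 846 and 244 against 456. Under the 3 scalings, the other probe set rules and the series matrix these 8 counts stayed within 1.5 times, and the series matrix, being identical, tests nothing. The balance of directions was less stable. For both treatments together 510 genes were higher and 390 lower, but 795 and 967 at a floor of 4, 941 and 1246 without a floor and 741 and 755 at 1.5-fold. For hypoxia with poly I:C 108 and 100 turned to 96 and 123 with reference gene centring, 207 and 221 at a floor of 4, 265 and 272 without a floor and 276 and 342 at 1.5-fold. For hypoxia in media 145 and 184 turned to 67 and 58 at 3-fold. Poly I:C in normoxia gave 402 and 194, but 642 and 636 without a floor, 482 and 133 with cyclic loess and 483 and 124 with reference gene centring. Poly I:C in hypoxia gave 447 and 261, but 504 and 172, and 505 and 171, with these scalings and 403 and 358 with median centring. Cyclic loess moved the median of all genes from -0.03 to 0.16 for poly I:C in normoxia, from -0.06 to 0.14 for poly I:C in hypoxia and from -0.10 to 0.15 for both together, and reference gene centring moved the first to 0.15 and the next to 0.12; the cause was not tested. Under these alternatives no list member or leading gene called at 2-fold and no list outside the middle 95% of random lists changed sign. Of the values of list members and leading genes, the only genes followed singly, 34 moved by 0.32 or more and 13723 by less. Many of the latter could not move. The identical series matrix gave 2361 of them, and the rule of a single probe set gave 1952, whose values it leaves unaltered. Each centring shifted all genes of a comparison by 1 constant, and none of its 2361 values moved that far. Cyclic loess moved 4 values and left 2357, and averaging probe sets moved 30 and left 2331. Of list medians 17 left the order-statistic interval of the reported value and 1279 stayed in it, 132 of them from the identical series matrix. Without matching 3 list percentiles crossed the edge of the middle 95% and 129 did not. These were maturation (4.82 to 2.14) and cholesterol genes (3.52 to 0.24) in hypoxia in media and amino acid response genes (94.02 to 98.84) for poly I:C in normoxia. Signal near background limits genes below the floor and every fold whose lower side is dim.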

Other observations

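In this part, the histone genes, the mitochondrially encoded genes outside the rule, Hif1a and the lower floor for cell cycle genes were picked after their values were seen.

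Histone and cell cycle genes were mostly highest on the untreated array. Poly I:C in normoxia, hypoxia in media and both together were all set against that 1 array, which also enters the difference of differences. These differences are therefore not independent of each other. A property of that culture cannot be told apart from an effect of the treatments. All but 1 of 17 histone genes above the floor were below the untreated array in both single treatments, with 11 at least 2-fold lower and a median of -1.08 with poly I:C in normoxia, and 11 lower and a median of -1.12 in hypoxia in media. H2bc4 was the exception. Since 8 of the 17 reached the floor on the untreated array only, they were admitted by being high there. The other 9 had 3 lower and a median of -0.81 with poly I:C in normoxia, and 3 lower and -0.98 in hypoxia in media. Without a floor the medians over 47 histone genes were -0.52 and -0.48. H3c13 was at -2.26 and -2.25 and H3c8 at -1.96 and -2.12. Between treated arrays the list was close to level, with medians of 0.23 for hypoxia with poly I:C and 0.28 for poly I:C in hypoxia, so 15 of the 17 had a difference of differences of 2-fold or more (median 1.37). Of the 9 genes above the floor on another array 7 did (median 1.18). Without a floor 18 of 47 were at least 2-fold above 0 and 1 below (median 0.62). Histone genes are near-identical copies, and their probe sets are not independent. Of 38 cell cycle genes only Rrm1 and Pcna reached the main floor, but 22 reached a floor of 4, and 17 of these did so on the untreated array only, which favours lower values elsewhere. Of the 22, 17 were lower with poly I:C in normoxia (median -1.93), 20 in hypoxia in media (-1.82) and 18 with both (-2.46), while 4 were lower for hypoxia with poly I:C (-0.26).

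Hif1a transcripts were lower in hypoxia in media (-1.75, 82.7 against 277) and in hypoxia with poly I:C (-1.0, 166 against 332). The reference genes had medians of -0.28 for poly I:C in normoxia, where cyclic loess gave 0.04, and -0.31 for poly I:C in hypoxia, where it gave -0.025, and among them Hprt was at -0.89 with poly I:C in normoxia. The authors' deposited table gives an order to 548 probe sets, and of these 237 were highest with hypoxia and poly I:C together, 142 with poly I:C in normoxia, 90 untreated and 79 in hypoxia in media.

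Most mitochondrially encoded transcripts were lower with poly I:C: over 9 genes the median was -1.54 in normoxia, with 6 genes at least 2-fold lower, and -2.03 in hypoxia, with 5 lower. They did not move alike. In normoxia ND3 was at -2.17, COX1 at -0.34 and ND6 at 0.37, and in hypoxia CYTB was at -2.87, COX1 at -0.36 and ND6 at -0.30. COX1, COX2, ATP6 and ND6, grouped after the values were seen, had medians of -0.61 and -0.46, and the other 5 genes -1.86 and -2.61. Intensity-dependent scaling of bright probe sets is argued against, since 13 nuclear genes as bright had a median of -0.0291 with poly I:C in normoxia (interval -0.40 to 0.45). For hypoxia with poly I:C the median over the 9 genes was -1.07, with 5 at least 2-fold lower, against -0.16 for the 13 nuclear genes. The 9 genes ranged from -1.84 for CYTB to 0.15 for ND6, and a dimmer ND3 probe set gave 0.12 where the brighter gave -1.23. With 1 array per condition, a difference in RNA quality between cultures stays open.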
